A study of Mus musculus with 6 samples.

How the data were processed

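Gene expression was measured by RNA sequencing in mouse bone marrow stromal cells of the C57BL/6 strain. Per the labels, marrow cells from tibia and femur were sorted as Sca-1+ CD29+ CD45− CD11b− and cultured in medium with 10% serum. The cells then received rGCA at 50 nM or PBS, the buffer control, for 3 days. RNA was taken with Trizol and sequenced as 150 bp paired-end reads, per the labels' protocols. There were 6 libraries, 3 per group, numbered 1 to 3 in the labels. No label says whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

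The deposited values are one number per Ensembl gene and library, and the unit is not named in the headers or labels. They were identified as FPKM (fragments per kilobase of exon, scaled to the library total) from the values deposited by the authors. Multiplied by the exon-union length of the gene in GENCODE M21, 92.8% of matched values were whole numbers of fragments, within 0.02 fragment, over a single whole-number total per library. Those totals ran from 17543509 to 18645932, a 1.06-fold range, so depth differed little between libraries. At such totals 1 fragment in a gene of 2 kb is worth 0.0268 to 0.0285 FPKM. The fragments so recovered sum to 18857245 to 19869327, above the totals in the denominators, and the reason was not tested. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm9 were named. The counting tool, annotation and filters are not given in the sources used here. The lengths fit GENCODE M21, which is on GRCm38, not on either named build. Coordinates are therefore those of GENCODE M21 on GRCm38, attached by Ensembl identifier, and the build of the authors' alignment remains open. How reads shared by near-identical genes, overlapping genes or opposite strands were assigned is not given in the sources used here.

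The files list 27263 genes, of which 27204 matched GENCODE M21 and 59 did not. The main test was limma-trend (limma 3.58.1 in R 4.3.3), with robust moderation, on log2(FPKM + 1). It covered the 11984 genes with a mean of at least 1 FPKM over the 6 libraries. Treatment was the only term, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every fold change in log2 units is on the log2(FPKM + 1) scale, which understates changes of low genes. Adjusted p-values of genes are from this fit. On simulated data with known answers over 11890 genes, drawn for the GCA against PBS comparison, the step called 86.5% of genes changed 1.5-fold and 97% of genes changed 2-fold. It called 0.15% of unchanged genes, which was 18 genes, beside the 83 and 96 changed genes called. The simulation drew each gene independently with 1 common dispersion of 0.0026, the median over genes. Real genes differ in spread, so these rates may be optimistic.

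Before the data were examined, 37 gene lists were fixed from general knowledge: 24 functional, 10 of cell type markers and 3 of sample composition. The 31 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, stand beside it. The version with an estimated correlation also takes its degrees of freedom from the few libraries rather than from the many genes. A call lost there need not be due to correlation between genes. The rule for named genes, fixed at the same time, took 3 kinds of gene. The first was the 10 genes with the largest rise and the 10 with the largest fall, among those past the threshold whose groups did not overlap, leaving out predicted genes. The second was up to 4 members of each list with the smallest p. The third was a fixed set of genes of bone, fat, senescence and the treatment itself. Other list members are given as examples. Some genes that the rule takes are not reported here.

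The alternatives fixed beforehand were the replicate number as a block, quantile normalization, median centring, other filters, other pseudocounts, limma without trend and robust moderation, other thresholds and leaving out each library. Alternatives chosen after seeing the data were limma-voom on the recovered fragments, a fit to protein-coding genes alone, and quantile normalization for the count of macrophage genes away from their list mean. A count model was not the main test because the deposited values are not counts. No 2 libraries of a group agreed within the sampling noise of fragments: the mean chi-square per gene between recovered fragments was 6.75 to 8.13 within PBS, 9.25 to 26.9 within GCA and 31.94 to 40.34 between groups. The median term of a gene was lower, at 0.97 to 1.53 within PBS, 1.24 to 1.94 within GCA and 3.07 to 3.75 between groups. Percent identity of gene segments was computed with Biostrings 2.70.1, and tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.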

Results

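The series asked how GCA acts on bone marrow stromal cells, the adherent marrow cells that give rise to bone and fat cells. From knowledge of the study rather than its labels, GCA is taken to be grancalcin, a calcium-binding protein of myeloid cells, and rGCA its recombinant form. Transcript levels were compared between 3 libraries of PBS-treated and 3 of GCA-treated cells. The totals behind the FPKM values were 18229435, 18157084 and 17828862 fragments for PBS replicates 1 to 3 and 17857566, 17543509 and 18645932 for GCA replicates 1 to 3. Correlations of log values were 0.989 to 0.994 within groups and 0.981 to 0.985 between groups, across genes, which are not independent replicates. The first principal component held 52.3% of the variance and separated the groups. The second held 16.2%, with GCA replicate 2 at 15 and GCA replicate 3 at −10.2. The most abundant entry, Gm23935, a short RNA annotated as a microRNA, took 6.41% to 12.33% of all FPKM.

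GCA-treated cells showed many small changes and few large ones. Of 11984 genes tested, 2151 (17.9%) passed an adjusted p of 0.05 (limma), 1380 higher and 771 lower with GCA. The median absolute log2 fold change of these genes was 0.33, and 66 of them changed by at least 1 log2 unit, 42 up and 24 down. Among the tested genes, 4612 (38.5%) had 3 GCA values all on one side of the 3 PBS values, against 10% by chance. Quantile normalization gave 1198 higher and 1027 lower, so the share of higher calls was 53.8% there and 64.2% in the main fit. The count was 1307 without PBS replicate 2, 1225 without PBS replicate 3 and 1361 without GCA replicate 1. It was 2078 without GCA replicate 2.

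Transcripts of macrophages were abundant in every library, although the sort was for CD45− CD11b− cells. Lyz2, the macrophage lysozyme, stood at 13520 ± 814 FPKM in PBS and 8879 ± 807 in GCA (SD, n = 3 each). The complement gene C1qa stood at 1487 FPKM in PBS and 1921 in GCA, and the lysosomal marker Cd68 at 614 ± 13.4 and 944 ± 105. Ptprc, which encodes CD45, was at 12.6 and 13.4 FPKM, and Itgam, which encodes CD11b, at 39.3 and 30.5. Collagen Col1a1, a stromal product, was at 1333 ± 94.6 and 1149 ± 53.8 FPKM. The 20 genes of the monocyte and macrophage list held 6.32% of FPKM in PBS and 5.41% in GCA, and the 19 without Lyz2 held 2.51% and 2.93%. Of these 20 genes 10 rose, among them Cd68, Mrc1, C1qa and Laptm5, 1 fell (Lyz2) and 9 did not pass. Adjusted over the list alone, 10 rose and 2 fell. The fall of Lyz2 by 0.61 log2 units was −0.11 (adjusted p = 0.438) after quantile normalization. Lyz2 kept its call under the other alternatives run for it, median centring among them. The list passed camera (adjusted p = 0.042) and fry (0.0465), with an adjusted p = 0.533 with an estimated correlation. The camera adjusted p was 0.0923 without PBS replicate 1, 0.0536 without PBS replicate 3, 0.179 without GCA replicate 2 and 0.0534 with a filter at a mean of at least 5 FPKM.

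**Figure D1:**
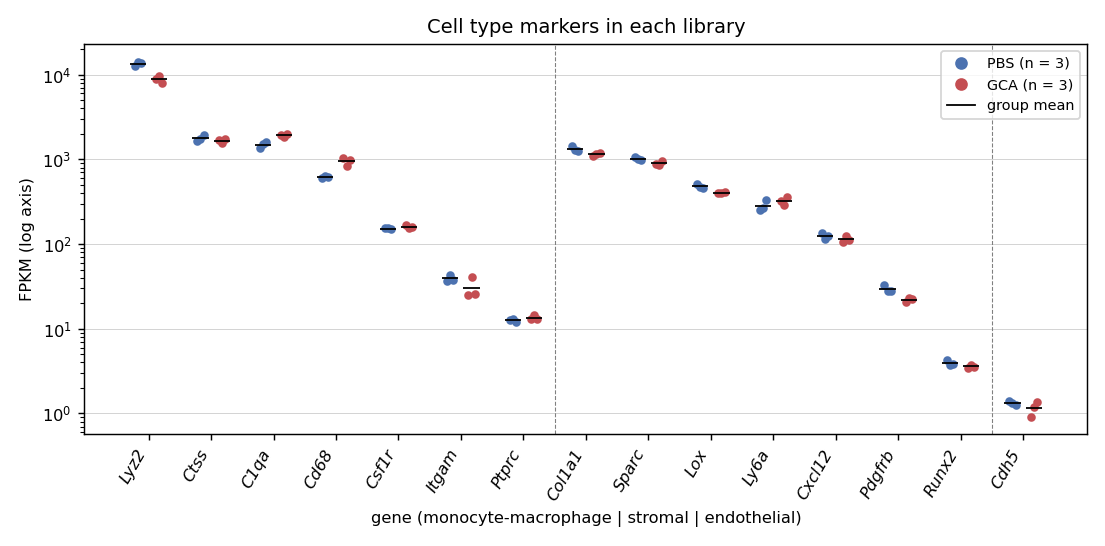
FPKM on a log axis of markers of macrophages, stromal cells and endothelium in each library; points are libraries (3 PBS, 3 GCA) and bars are group means. Lyz2 is the highest marker shown at 13520 FPKM in PBS, while the endothelial gene Cdh5 lies near 1.33 FPKM.

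Markers of other lineages were mostly low. Of the T and NK cell list, 1 of 14 genes was tested, Cd4, which rose from 1.62 to 4.13 FPKM. Of the B cell list 3 of 12 were tested: Cd22 rose from 1.38 to 3.38 FPKM, Blnk rose from 3.72 to 6.37, and Ebf1 was at 4.94 and 4.68. The endothelial list had 2 of 15 genes tested, the erythroid list 1 of 15 and the myogenic list 0 of 12, with none past the threshold. In the megakaryocyte list 3 of 10 genes were tested and Pf4, a platelet chemokine that macrophages also make, rose from 29.6 ± 3.80 to 74.2 ± 4.56 FPKM. In the neutrophil list 6 of 17 were tested, Csf3r rose, Chil3 fell and 4 did not pass (camera adjusted p = 0.305). Csf3r had an adjusted p of 0.0863 without PBS replicate 2, 0.0805 without PBS replicate 3, 0.0879 without GCA replicate 1 and 0.0722 without GCA replicate 2. In the osteoclast list 2 of 7 tested genes rose, Nfatc1 and Atp6v0d2 (camera adjusted p = 0.278, fry 0.0492, and p = 0.533 with an estimated correlation), and in the list of pericyte and smooth muscle genes 2 of 7 fell, Acta2 and Notch3 (0.197). Leaving out PBS replicates 1, 2 or 3 or GCA replicate 1 ended the calls of Acta2 (adjusted p = 0.0601 to 0.0836), Nfatc1 (0.0537 to 0.0661) and Atp6v0d2 (0.0551 to 0.0942). So did GCA replicate 2 for Nfatc1 (0.0509) and GCA replicate 3 for Atp6v0d2 (0.0845).

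On the log2(FPKM + 1) scale, with predicted genes left out, the largest rise past the threshold was of Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), a hyaluronan receptor of lymphatic vessels and some tissue macrophages. It went from 3.41 ± 0.33 to 22.7 ± 4.99 FPKM, 6.65-fold by means, with a log2 fold change of 2.40 (SE 0.161, adjusted p = 0.000503). By the ratio of group means Il1a rose more, 7.57-fold. Fgl2 (ENSMUSG00000039899, chromosome 5, 21372642 to 21378374), a fibrinogen-like protein, rose 4.92-fold from 9.44 ± 0.74 to 46.4 ± 1.30 FPKM (log2 2.19, SE 0.061, adjusted p = 3.46e-06). The chemokine Ccl8 rose 3.61-fold from 26.5 ± 2.76 to 95.7 ± 17.4 FPKM, and the lectin Clec10a rose 3.83-fold from 3.36 ± 0.71 to 12.9 ± 2.20. Abcg3 rose 5.04-fold, the transcription factor Ascl2 5.07-fold and the guanylate-binding protein Gbp8 6.42-fold, each from under 1.5 FPKM. The other rises among these 10 genes were of T cell receptor alpha variable segments on chromosome 14. Trav13n-4 (53362267 to 53364106) rose 6.58-fold, Trav14n-3 (53370077 to 53370575) rose 6.67-fold and Trav14-3 (53763173 to 53763694) rose 3.20-fold. These segments are uncertain, because the Trav14n-3 and Trav14-3 transcripts match over 98.2% of aligned bases and reads could be shared. Trav14-3 had an adjusted p of 0.0303, which was 0.061 without PBS replicate 2, 0.0777 without PBS replicate 3, 0.116 without GCA replicate 1 and 0.0534 without GCA replicate 3.

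On the same scale the largest fall was of Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine transporter that feeds glutathione synthesis. It went from 15.7 ± 2.41 to 2.54 ± 2.29 FPKM, 6.19-fold lower (log2 −2.42, SE 0.442, adjusted p = 0.0188). GCA replicate 2, at 5.167 FPKM against 1.508 and 0.9399 in GCA replicates 1 and 3, limits that fold, which was 12.8 without it. Its adjusted p was 0.0563 without PBS replicate 2, 0.068 without PBS replicate 3 and 0.0825 without GCA replicate 1. The organic anion transporter Slco4a1 went from 6.36 ± 0.90 to 0.67 ± 0.49 FPKM, a larger fall by the ratio of group means (9.55-fold, and 16.4-fold without GCA replicate 2), the stress pseudokinase Trib3 from 14.01 ± 0.87 to 3.99 ± 1.82 and the glutathione transferase Gsta3 from 10.5 ± 0.79 to 3.16 ± 0.68. The neutrophil chemokine Cxcl5 fell by 1.47 log2 units and the chitinase-like protein Chil3 by 1.44. Lipoprotein lipase, Lpl (chromosome 8, 68880491 to 68907448), went from 16.1 ± 0.88 to 5.67 ± 0.75 FPKM. Osteopontin, Spp1 (chromosome 5, 104435118 to 104441050), went from 3889 ± 511 to 1655 ± 155 FPKM (log2 −1.23, SE 0.105, adjusted p = 0.000518). Cox6a2 and the zinc transporter Slc39a4 also fell, with adjusted p = 0.0149 and 0.0255. Without PBS replicates 2 and 3 in turn that of Cox6a2 was 0.0527 and 0.0589. That of Slc39a4 was 0.0571, 0.0758 and 0.0766 without PBS replicates 1, 2 and 3 and 0.086 without GCA replicate 1.

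**Figure D2:**
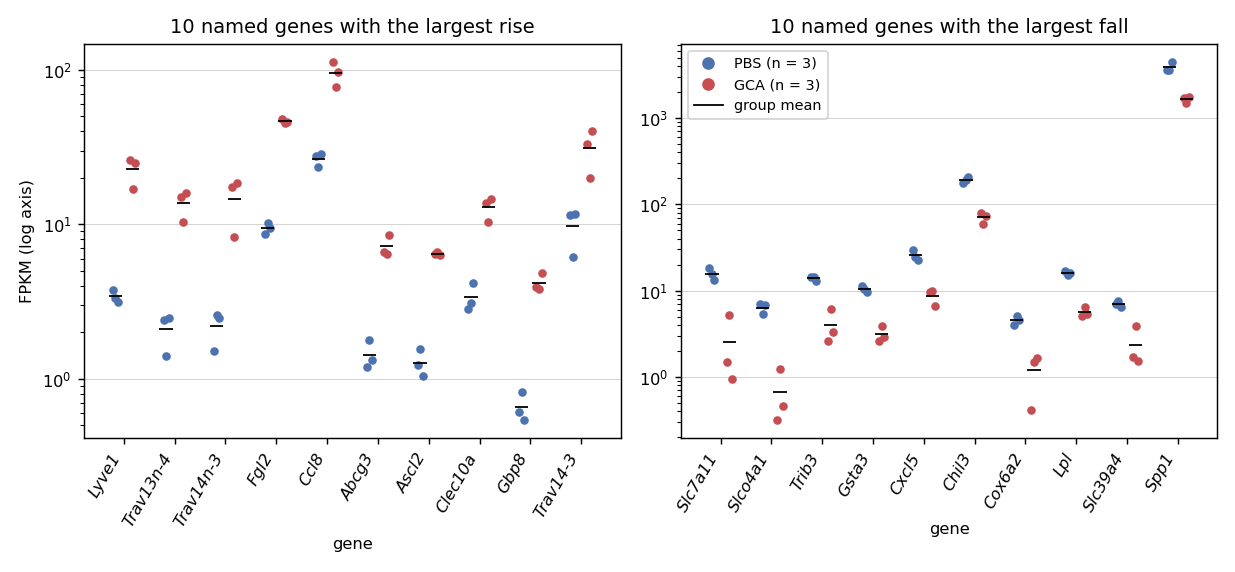
FPKM on a log axis of the 10 named genes with the largest rise (left) and fall (right) with GCA, ranked by log2 fold change; points are libraries (3 per group) and bars are group means. The groups do not overlap for any gene shown, and Lyve1 moves from 3.41 to 22.7 FPKM on average while Spp1 moves from 3889 to 1655.

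In the list of the antioxidant response driven by NRF2, of 21 genes tested, 14 fell, 1 rose (Mt1) and 6 did not pass, with a median log2 fold change of −0.33. Adjusted over the list alone, 14 fell and 1 rose. The summed FPKM of the list was 13060 in GCA replicate 2, above each PBS library (11730 to 12350), against 10250 and 9049 in GCA replicates 1 and 3, with ferritin (Fth1), which did not pass, at 10911, 8212 and 7058.2 in GCA replicates 2, 1 and 3. Gclm, a subunit of the enzyme that starts glutathione synthesis, went from 32.9 ± 1.48 to 14.9 ± 1.62 FPKM, catalase (Cat) from 171 ± 11.2 to 95.5 ± 0.57 and thioredoxin reductase (Txnrd1) from 33.5 ± 2.25 to 20.7 ± 0.59. The list passed camera (adjusted p = 1.09e-10) and fry (0.000853), with an adjusted p = 0.108 with an estimated correlation. In the unfolded protein response list, 6 of 24 genes fell and none rose, with 7 lower and 1 higher adjusted over the list alone. The 6 were Atf4, a transcription factor of amino acid and endoplasmic reticulum stress, with Ddit3, Trib3, Chac1, Asns and Ero1l. Asns, which makes asparagine, went from 24.1 to 14.8 FPKM, and Chac1, which degrades glutathione, from 5.72 to 2.09. That list passed camera (adjusted p = 0.0408) but not fry (0.179), with an adjusted p = 0.637 with an estimated correlation. The camera adjusted p was 0.162 without PBS replicate 2, 0.153 without GCA replicate 3 and 0.0785 with a filter at a mean of at least 5 FPKM.

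Genes of cell division rose. Of 36 tested, 31 rose, none fell and 5 did not pass, and 35 rose adjusted over the list alone. The median log2 fold change was 0.43. The proliferation marker Mki67 rose from 9.37 ± 0.25 to 14.01 ± 0.54 FPKM, cyclin Ccnb2 from 8.30 ± 0.59 to 15.6 ± 1.06 and survivin (Birc5) from 4.02 ± 0.24 to 7.41 ± 0.35. The list passed camera (adjusted p = 7.05e-18) and fry (0.00398), with an adjusted p = 0.494 with an estimated correlation. Replication histones, whose transcripts mostly lack a poly(A) tail, had 6 tested members: Hist1h2ab fell and 5 did not pass (camera adjusted p = 0.0207, fry 0.0573, and p = 0.498 with an estimated correlation). There were 2 lower adjusted over the list alone. Hist1h2ab had an adjusted p of 0.0501, 0.0816 and 0.0759 without PBS replicates 1, 2 and 3 and 0.0676 without GCA replicate 3. In the list of senescence and p53 genes, 4 of 22 rose and 4 fell (camera adjusted p = 0.319). Sesn1, Gdf15 and the nuclear lamin Lmnb1 rose, and Fas fell. Cdkn1a, the p21 inhibitor, stood at 202 and 227 FPKM (adjusted p = 0.0391), with adjusted p-values of 0.111, 0.139, 0.124 and 0.104 without PBS replicate 2, PBS replicate 3, GCA replicate 1 and GCA replicate 3. Cdkn2a, the p16 and p19 locus, was at 126 ± 6.29 and 125 ± 12.5 FPKM and did not pass.

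Genes of cholesterol synthesis rose. Of 23 tested, 16 rose, none fell and 7 did not pass, with 19 higher and 1 lower adjusted over the list alone. Mvd, of the mevalonate pathway, rose from 23.1 ± 2.08 to 39.7 ± 2.76 FPKM, and Dhcr7, of the last step to cholesterol, from 6.81 ± 0.59 to 11.6 ± 0.87. The median log2 fold change was 0.28 (camera adjusted p = 7.86e-08, fry 0.0225, and p = 0.498 with an estimated correlation). Glycolytic and hypoxia-related genes fell in 11 of 27 and rose in 2, Car9 and Pfkfb4. Adjusted over the list alone, 18 fell and 2 rose. Pyruvate kinase (Pkm) went from 315 ± 7.23 to 191 ± 24.3 FPKM and the glucose transporter Slc2a1 from 14.9 to 9.07 (camera adjusted p = 5.14e-07, fry 0.0492, and p = 0.498 with an estimated correlation). In oxidative phosphorylation 2 of 30 genes rose, Sdhc and Sdhd (camera adjusted p = 0.305), and both calls were fragile. Sdhc had an adjusted p of 0.0806 after quantile normalization, 0.0554 after median centring and 0.0602 to 0.118 on leaving out any 1 of the 6 libraries. Sdhd had 0.0532, 0.0743 and 0.0658 without PBS replicate 1, PBS replicate 2 and GCA replicate 1.

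Extracellular matrix genes fell. Of 26 tested collagens, elastic fiber genes and cross-linking enzymes, 14 fell, 1 rose (Fmod) and 11 did not pass, with 20 lower and 1 higher adjusted over the list alone. Col3a1 went from 244 ± 18.3 to 171 ± 13.6 FPKM, fibronectin (Fn1) from 487 ± 34.7 to 359 ± 15.2 and the cross-linking enzyme Loxl2 from 42.7 ± 1.61 to 32.8 ± 1.27. The median log2 fold change was −0.27 (camera adjusted p = 6.25e-09, fry 0.0358, and p = 0.498 with an estimated correlation). In the macrophage list 10 of 20 genes rose in these libraries, among them Cd68, 1 fell, Lyz2, and 9 did not pass. The call of Lyz2 was lost after quantile normalization but not after median centring, as given above. In the actin and YAP target list 3 of 22 genes fell, Flna, Tpm1 and Acta2, and none rose (camera adjusted p = 5.5e-06, fry 0.0859, and p = 0.499 with an estimated correlation). With adjustment over the list alone 11 fell and none rose. Leaving out any PBS library or GCA replicate 1 ended the calls of Tpm1 (adjusted p = 0.0597 to 0.101) and Acta2 (0.0601 to 0.0836), and Tpm1 had 0.0611 without GCA replicate 2. In the list of stromal progenitor and niche genes 5 of 22 fell, including Bst1 (96.4 to 48.3 FPKM) and Pdgfrb (29.29 to 21.95), and Vcam1 rose from 28.6 to 53.1, with 5 lower and 2 higher adjusted over the list alone. That list passed camera (adjusted p = 0.0386) but not fry (0.0859), with an adjusted p = 0.498 with an estimated correlation. Its camera adjusted p was 0.0923 without PBS replicate 1, 0.0554 without PBS replicate 3, 0.0518 without GCA replicate 2 and 0.0568 after quantile normalization.

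Osteogenic genes moved both ways. Of 20 tested, 4 rose (Sp7, Ibsp, Pth1r and Smpd3), 5 fell (Spp1, Atf4, Bglap2, Col1a2 and Ank) and 11 did not pass (camera adjusted p = 0.197, fry 0.0492, and p = 0.499 with an estimated correlation). Spp1 is also a gene of lipid-associated macrophages, and Atf4 is also in the unfolded protein response list. Which cells carry these falls was not tested. Adjusted over the list alone, 5 rose and 8 fell. Sp7, the osteoblast transcription factor osterix, was at 1.39 ± 0.34 and 2.71 ± 0.23 FPKM, and bone sialoprotein Ibsp at 162 and 268. Runx2 at 3.93 and 3.59, Alpl at 7.22 and 7.78 and Col1a1 did not pass, and Bglap, at 0.57 and 0.36 FPKM, was below the filter. In the adipogenic list 3 of 19 fell, Lpl, Cd36 and Plin2, none rose and 16 did not pass (camera adjusted p = 0.0522, fry 0.0123, and p = 0.498 with an estimated correlation), with 3 lower adjusted over the list alone. Lipid-laden macrophages also express these 3 genes. In the same libraries 10 of 20 macrophage list genes rose, 1 fell and 9 did not pass. The lipid droplet protein Plin2 had an adjusted p of 0.0179, which was 0.0553 without PBS replicate 2, 0.0645 without PBS replicate 3 and 0.0595 without GCA replicate 3. Pparg at 5.07 and 5.59, Cebpa at 35.7 and 38.6 and Fabp4 at 25.1 and 27.1 FPKM did not pass. Adipoq, at 0.54 and 0.42, was below the filter. Of 5 tested chondrogenic genes Col2a1 rose and Col11a1 fell (camera adjusted p = 0.72).

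Interferon-induced genes rose in part. Of 30 tested, 10 rose, none fell and 20 did not pass, and 12 rose adjusted over the list alone. The transcription factor Irf7 rose from 88.8 ± 4.42 to 134 ± 8.59 FPKM and the immunoproteasome subunit Psmb9 from 6.88 ± 0.56 to 12.9 ± 0.78. The list passed camera (adjusted p = 5.14e-07) but not fry (0.0709), with an adjusted p = 0.533 with an estimated correlation. Libraries stood apart within groups: the median log2 difference of the 30 genes from their PBS mean was 0.185, −0.052 and −0.13 in PBS replicates 1 to 3 and 0.492, 0.202 and 0.234 in GCA replicates 1 to 3. Of 18 inflammatory cytokines and chemokines 2 rose, Ccl8 and Il1a, and 2 fell, Cxcl5 and Ccl20 (camera adjusted p = 0.606). Ccl20 had an adjusted p of 0.0502 to 0.0971 without any 1 of the PBS libraries, GCA replicate 2 or GCA replicate 3. Il1a went from 0.42 ± 0.19 to 3.18 ± 0.95 FPKM, and Il6, at 0.43 and 0.25, was below the filter. Of 21 NF-kB targets 1 rose, Vcam1 (camera adjusted p = 0.838). GCA replicate 2 stood apart from the other GCA libraries in inflammatory transcripts chosen after their values were seen. Its Lcn2 was 141 FPKM against 10.8 and 7.77 in GCA replicates 1 and 3, and its Saa3 was 4061 against 1834 and 1446.

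**Figure D3:**
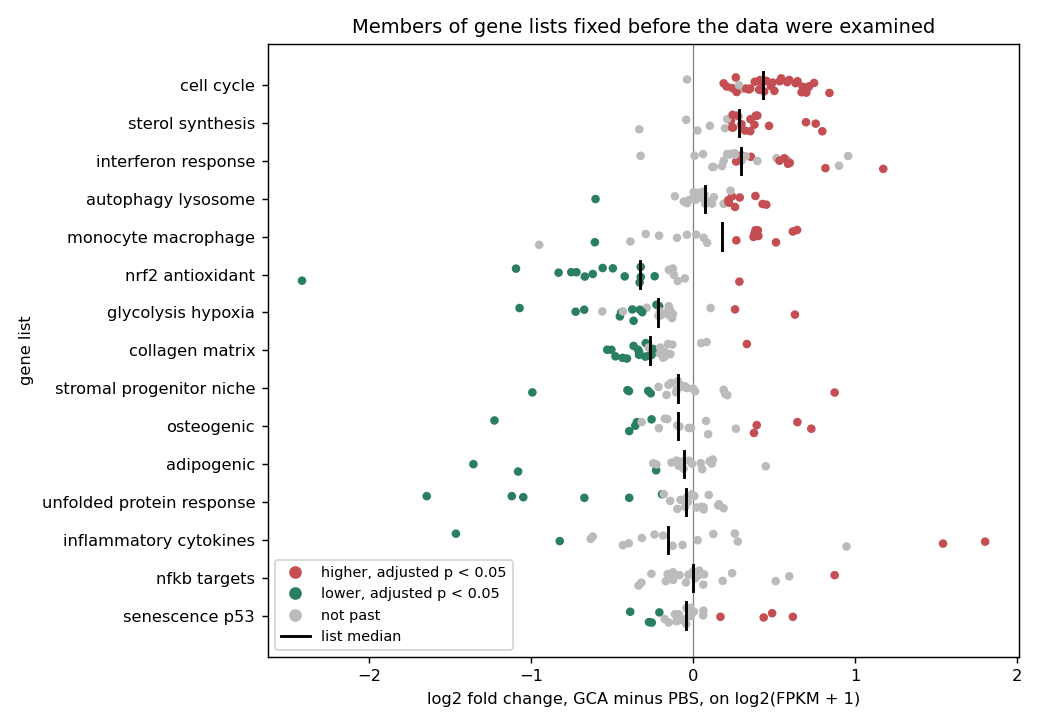
Log2 fold change (GCA minus PBS, on log2(FPKM + 1)) of each tested member of 15 gene lists; points are genes, colored by whether they passed the gene test, and bars are list medians. The cell cycle median lies at 0.43, the NRF2 median at −0.33 and the matrix median at −0.27.

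Lysosomal and autophagy genes rose in 8 of 28, among them Ctsb and Hexa, while the autophagy receptor Sqstm1 went from 229 ± 11.2 to 150 ± 5.50 FPKM. Adjusted over the list alone 9 rose and 1 fell. The list passed camera (adjusted p = 0.0386) but not fry (0.0859), with an adjusted p = 0.536 with an estimated correlation. Its camera adjusted p was 0.0923 without PBS replicate 1, 0.0592 without PBS replicate 2, 0.068 without GCA replicate 1, 0.0766 without GCA replicate 3 and 0.0694 after quantile normalization, under which Ctsb lost its call (adjusted p = 0.112). Cd68, another lysosomal protein of macrophages, rose in the same libraries, where 10 of 20 macrophage list genes rose, 1 fell and 9 did not pass. Of 48 cytosolic ribosomal protein genes 4 fell, among them Rpl23, Rpl5 and Rpl8, and none rose (camera adjusted p = 2.44e-08, fry 0.0859, and p = 0.533 with an estimated correlation). With adjustment over the list alone none passed, at 0 lower and 0 higher. Rpl23, Rpl5 and Rpl8 each lost their call without PBS replicate 2, PBS replicate 3, GCA replicate 1 or GCA replicate 3 (adjusted p = 0.0663 to 0.159), and Rpl8 also without GCA replicate 2 (0.0784). Of 12 mitochondrially encoded genes 3 fell, mt-Nd6, mt-Co3 and mt-Atp6 (camera adjusted p = 0.00116, fry 0.0945, and p = 0.533 with an estimated correlation). There were 5 lower adjusted over the list alone. Without PBS replicate 2 the adjusted p of the 3 genes was 0.103, 0.058 and 0.0527. Without PBS replicate 3 it was 0.0844 for mt-Nd6 and 0.0543 for mt-Atp6, and without GCA replicate 1 it was 0.0511 for mt-Nd6 and 0.0527 for mt-Co3. The values of mt-Co3 and mt-Atp6, at 16.0 and 11.1 FPKM in PBS against 489 for mt-Nd6, are uncertain because reads can be shared with nuclear copies.

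The remaining lists did not pass camera. Of 24 plexin and semaphorin genes 2 rose, Sema7a and Nrp1, and 1 fell, Plxna1 (adjusted p = 0.305), whose gene call was lost on leaving out any 1 library (0.0553 to 0.117). Of 26 genes of BMP and TGF-beta signaling 4 rose, including Id2, and 3 fell, including Inhba (0.287). Of 18 Wnt genes 4 fell, including Ccn4 and Wnt5a (0.182), of 10 Notch genes 3 fell and 1 rose (0.123), and of 20 matrix proteases 1 fell, Mmp2 (0.107), with a gene adjusted p of 0.0656 without GCA replicate 1 and 0.0518 without GCA replicate 3. Of 21 immediate early genes 3 fell, including Atf3, and 1 rose (0.287), and of 21 genes of the insulin and IGF axis 2 rose, including Ddit4, and 2 fell (0.606). With adjustment over the list alone, the plexin and semaphorin list had 2 higher and 0 lower, the BMP and TGF-beta list 4 and 5, the immediate early list 1 and 4, and the insulin and IGF list 3 and 2. The Wnt, Notch and protease lists kept their counts. In lists given further above, 0 oxidative phosphorylation genes passed so adjusted, and there were 4 senescence genes higher and 5 lower, 2 cytokines higher and 3 lower, and 2 chondrogenic genes each way. The endogenous Gca transcript was at 3.34 FPKM in PBS and 4.79 ± 0.42 in GCA (log2 0.41, SE 0.068, adjusted p = 0.0058). Plxnb2, which encodes plexin-B2, was at 80.3 ± 1.71 and 76.3 ± 3.53 FPKM (adjusted p = 0.33).

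No list passed with an estimated correlation, and 9 passed fry. Camera with the preset correlation called 14 lists here and as many on another split of the 6 libraries, so its p-values weigh less than the counts of genes. Comparisons rest on 3 libraries per group.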

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

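All 2151 main calls that were tested in an alternative kept their sign there, and quantile normalization and median centring moved the median of all genes by under 0.1 log2 units. Limma-voom on recovered fragments and the fit to protein-coding genes alone were chosen after seeing the data, and gave 2660 and 2451 genes. Depth was even, at 17543509 to 18645932 fragments, and genes near 1 FPKM are the least precise. Whether replicate numbers pair the libraries stays open. With the group means removed, same-numbered libraries correlated at only 0.082, 0.029 and 0.068. Yet each PBS library correlated best with the GCA library of its own number, and the reverse. With 3 libraries per group such a match can arise by chance, so it does not decide on pairing. With the replicate number as a block 2094 genes passed, 1844 of them shared with the main fit, and the macrophage list (adjusted p = 0.0805), Slc7a11 (0.0753), Trav14n-3 (0.0655), Cdkn1a (0.0619), Hist1h2ab (0.0783), Sesn2 (0.0625) and Rpl8 (0.066) no longer passed.

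Without a filter, with 27263 genes tested, 1075 passed (735 higher, 340 lower). An adjusted p below 0.01 gave 837 (591 higher, 246 lower), below 0.10 gave 1258 lower, and a log2 fold change of at least 1 gave 66 (42 higher, 24 lower). Leaving out 1 library gave 1225 to 2078 genes, 841 to 1310 higher and 384 to 768 lower. Camera called 14 lists, and 0 (0 higher, 0 lower) with an estimated correlation. Fry called 9, of which 5 were lower: 6 of the 14, with the osteogenic, adipogenic and osteoclast lists besides. With a filter at a mean of at least 5 FPKM the macrophage (camera adjusted p = 0.0534) and unfolded protein response (0.0785) lists no longer passed. Leaving out 1 library gave 3 to 4 higher lists against 5, the 3 being without PBS replicate 1. Among 119 named genes called, 82 kept their call under all 13 alternatives run for them, and none of the 119 reversed. Of 37 named genes that did not pass, 16 passed under at least 1 alternative, 13 with limma-voom and 14 under one fixed beforehand, among them Col1a1 with median centring (adjusted p = 0.0467) and a mean of at least 5 FPKM (0.0431). Among named genes that did not pass, Eng was −0.007 after quantile normalization and −0.002 after median centring, against 0.011, and −0.024 to 0.076 on leaving out 1 library. Cdkn2a was −0.097 to 0.032 on leaving out 1 library, against −0.016. The number of macrophage genes far from their list mean, an alternative also added after seeing the data, was 10 after quantile normalization against 11. The causes were not tested.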

Other observations

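The tests on ATF4 targets, resident and lipid-associated macrophage genes, composition, T cells, scaling, endotoxin and single libraries, and the splits for genes and camera lists, were chosen only after the results were seen. Beyond the fixed lists, genes of amino acid supply fell with GCA. In a list of ATF4 targets written after the data were seen, 25 of 28 tested genes fell and none rose, with a median log2 fold change of −0.38. The serine synthesis enzyme Phgdh went from 33.6 ± 1.4 to 19.4 ± 2.6 FPKM (SD, n = 3), the amino acid transporters Slc38a2 from 71.3 to 35.5 and Slc7a5 from 11.2 to 6.54, and Atf5 from 52.9 to 28.6. Members of the fixed lists, named genes and genes seen before the list was written were then set aside. Of the 19 others 17 fell, which is 89.5%, consistent with a fall of the program beyond the genes that led to it. Those 19 passed fry (adjusted p = 0.00158), with an adjusted p = 0.092 by camera with an estimated correlation.

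Several of the largest rises are genes of tissue-resident macrophages. In a list of such genes, also written after the data were seen, 15 of 24 tested genes rose and 2 fell. Cbr2 rose from 269 to 473 FPKM, Selenop from 1336 to 2078, P2ry13 from 5.38 to 15.5 and the transcription factor Maf from 45.0 to 60.8, while F13a1 fell from 394 to 308. Of the 15 members left after the same genes were set aside, 6 rose, which is 40%, and 2 fell (fry adjusted p = 0.29, and camera adjusted p = 0.798 with an estimated correlation), so the list leaves open whether the rise extends beyond the genes that drew attention. Cd163 at 23.0 and 22.6 and Stab1 at 180 and 183 FPKM did not pass. In further lists written after the data were seen, 2 of 16 genes of lipid-associated macrophages rose and 6 fell, 3 of 8 genes of alternative activation rose and 3 fell, and 1 of 4 class II genes rose and 0 fell. Of the lipid-associated genes 9 were left after the same genes were set aside (fry adjusted p = 0.29, and camera adjusted p = 0.798 with an estimated correlation). In the other 2 lists fewer than 5 were left, and none was tested as a list.

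The 6 libraries split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 2151 genes and the highest other 0. By fry it called 9 lists and the highest other 0. By camera it called 14 lists, and 2 of the 10 splits, the real one included, called as many. The other grouped PBS replicates 1 and 3 with GCA replicate 3. Every split except the real one puts both treatments in each group. Such a split keeps part of the treatment difference and adds to the spread within groups. Its counts therefore do not show what would be called without a treatment difference.

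In the macrophage list 10 of 20 genes rose and 1 fell, and in the matrix list 14 of 26 fell and 1 rose, which a change in cell composition could produce. With an estimated correlation the adjusted p was 0.533 and 0.498, and the macrophage list held a smaller share of FPKM with GCA (5.41% against 6.32%), a fall carried by Lyz2, since the other 19 genes held 2.93% against 2.51%. If macrophages of 1 uniform kind had only become more frequent, and no other cell made these genes, the genes would share 1 shift. Yet 11 of the 20 macrophage genes lay more than 3 of their own standard errors from the list mean. After quantile normalization 10 did, and there Cd68 stood at 0.51 and Ctss at −0.31 log2 units. In the main fit Cd68 stood at 0.614 and Ctss at −0.101, so the lower value of Ctss came mostly with that normalization. The spread argues against that simple case as the whole cause. A changed mix of macrophages, or expression of these genes in other cells, stays open. For the matrix, the median log2 fold change was −0.162 relative to that of other stromal genes (95% bootstrap interval −0.25 to −0.058). The interval resampled genes as if independent, not libraries, while the estimated correlation within the matrix list was 0.381. It therefore does not decide whether a lower stromal share is the whole cause. The other stromal genes had a median of −0.104, and part may be share. After quantile normalization 13 of the 14 matrix calls remained lower. The 14 were chosen as lower in the same data. Quantile normalization also raised the lower calls over all genes, to 1027 from 771, so this count does not decide on scaling. A response of the cells to the treatment stays open as a hypothesis.

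The segments Trav13n-4, Trav14n-3, Trav13-4-dv7 and Trav14-3 rose, while Trav14-2 fell from 4.43 to 3.21 FPKM (adjusted p = 0.0346) and Trav4-3, at 1.75 and 1.07, did not pass. The constant region Trac reached at most 0.00829 of the level of Trav13-4-dv7 in a GCA library, which argues against T cells as the source. Trav13n-4 matches Trav13-4-dv7 over 93% and Trav14n-3 matches Trav14-3 over 98.2% of aligned bases, so it stays open how much of the rise of each segment may be reads from its copy. Apart from T cells as the source, no biological explanation was tested.

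In the interferon list 10 of 30 genes rose and 20 did not pass (adjusted p = 0.533 with an estimated correlation), and endotoxin in a recombinant protein could raise such genes. Over all 11984 tested genes 1380 rose. Of 22 tested endotoxin-induced genes 9.1% rose and none fell, with a median log2 fold change of −0.158. By the rule of this test only a joint fall of these genes would have counted against endotoxin. That test leaves endotoxin open, because 3 days of treatment may let an early response fade and because GCA replicate 2 stood apart in such genes. A few libraries also stay open as the source. The median log2 difference of the 30 genes from their PBS mean was 0.492, 0.202 and 0.234 in GCA replicates 1 to 3 and 0.185 in PBS replicate 1, a gap of 0.017, below the SD of the PBS libraries (0.164).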
